A study of Mus musculus with 9 samples.

How the data were processed

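Gene expression was measured by RNA sequencing in primary Leydig cells of wild-type mouse testis, in 9 libraries. Per the labels, 3 libraries came from control cells, 3 from cells exposed to triphenyl phosphate (TPhP) and 3 from cells exposed to diphenyl phosphate (DPhP). The labels describe an extraction with Trizol, enrichment of mRNA on oligo(dT) beads, fragmentation, cDNA synthesis and adaptor ligation. They do not say whether the library kit kept the strand, so overlapping and antisense genes could share reads. Doses and exposure times are not given in the sources used here. The labels also do not say that the 3 libraries of a group came from separate cultures or animals. If they did not, the p-values measure only the spread between these libraries, which may be technical.

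The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments) for 19058 genes, with Entrez gene identifiers and symbols. Values were given to 2 decimals, and 21 genes were at 0 in all libraries. Per the submitters' processing notes, the genome build was GRCm38.p6. The aligner, the counting tool, the annotation and any filter on genes are not given in the sources used here. FPKM values are not counts, so no count model was fitted. All 9 columns were matched to samples by their names, and no column was left unmatched.

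Read depth is not stated. Values near 0 were examined for steps of 1 read, but the step could be taken only from the same values, so neither the absolute depth nor the depth of the libraries relative to each other was established. No counting interval was derived.

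Values were analysed as log2(FPKM + 1). The pseudocount of 1 shrinks the fold changes of genes with low FPKM. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 12369 genes. All 9 libraries entered 1 linear model with a mean per group in limma 3.58.1 under R 4.3.3, with an intensity trend in the moderated variance and 6 residual degrees of freedom before moderation. Each comparison was adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The comparisons were TPhP against control, DPhP against control and TPhP against DPhP, all two-sided. Intervals are 95% intervals from the same model.

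Before the data were examined, 30 gene lists were fixed from textbook knowledge. They covered Leydig cell functions, lipid metabolism, stress and xenobiotic responses, cell growth, and markers of other cell types that a testis preparation can hold. The table held 669 of their 687 members, and 3 of these were matched through an older symbol. Genes encoded by the mitochondrial genome, which formed 1 list, were not analysed here, and the list of blood cell markers had 4 tested members and was given no set test. The other 28 lists had at least 5 tested members and were tested with camera, a competitive set test in limma, at a preset correlation of 0.01 between genes. Set tests with an estimated correlation, and with fry, were alternatives. Counts of members are given over all tested genes and, where stated, adjusted over the list alone.

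The genes named in the text were chosen by a rule fixed before the data were examined. It took, per comparison, the 7 called genes with the largest rise and the 7 with the largest fall. Candidates needed a mean of at least 1 FPKM over both groups and no overlap between the groups. Symbols with a Gm number or a Rik name were left out, while LOC symbols were not. The rule added a panel of 8 Leydig cell genes whatever their values, and up to 4 called members with the smallest p from each list. Genes outside the rule are marked as chosen after their values were seen. Results of some single genes are not reported here.

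Gene positions were taken from the RefSeq annotation of GRCm38.p6, which held 99.7% of the identifiers. GC content, transcript length and the share of 75-base stretches not found in transcripts of any other gene (called unique sequence here) were computed from GENCODE M21 transcripts, available for 97.1% of the genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for these steps and for the figures.

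Both comparisons with the control share its 3 libraries. Their correlation was therefore set beside 200 simulations of unchanged groups, and the overlap of calls beside that of independent lists. The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, rescaling to a common sum, median-of-ratios size factors, quantile normalization, a fit to the 6 libraries compared, a replicate block, a variance without trend, array weights, a minimum log2 fold change of 1, and leaving out each library. A restriction to genes with at least 90% unique sequence, and removal of trends with GC content and length by lowess with a span of 0.5, were added after the data were seen. Ranges and lost calls of single genes and lists are given over these alternatives of data and model, with the minimum fold change and the other set tests kept apart.

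The test was run on simulated data drawn with the control means and the residual spread of these libraries and 200 changed genes. For TPhP against control it recovered 55.2% of genes changed by a log2 fold change of 0.25, 89.6% at 0.5 and 98.5% at 1. For DPhP against control these shares were 58.2%, 92.5% and 97.0%, and for TPhP against DPhP 59.7%, 92.5% and 95.5%. False calls made up 6.36%, 5.17% and 4.62% of the calls in these simulations. The runs shared the control means, the spread and the number of changed genes, and differed only in the random draw and the groups compared. The real comparisons called 769, 8782 and 8495 genes. More changed genes make the adjustment less strict, so these shares do not give the sensitivity of the comparisons with DPhP. No library was left out, and no pair of libraries held identical values.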

Results

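The study asked which genes change in mouse primary Leydig cells, the testosterone-producing cells between the seminiferous tubules, after exposure to TPhP or DPhP. TPhP is an organophosphate flame retardant and plasticiser with phosphate esterified to 3 phenyl groups, and DPhP is its metabolite lacking 1 of these esters. Expression was given as FPKM in 3 control, 3 TPhP and 3 DPhP libraries. The sum of FPKM was 421963 to 428928 in control, 419107 to 422363 in TPhP and 398680 to 401930 in DPhP libraries. Between 11958 and 12120 genes reached 1 FPKM in a library. Genes listed at 0 numbered 1743 to 2002 in control, 1977 to 2066 in TPhP and 2444 to 2546 in DPhP libraries. The 10 most abundant genes held 5.79% to 5.96% of the sum in all 9 libraries.

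The DPhP libraries stood apart from the other 6. The first principal component held 86.9% of the variance and separated them, while the second, with 3.83%, separated TPhP from control. Pearson correlations across tested genes were 0.996 to 0.997 within groups and 0.995 to 0.996 between TPhP and control libraries. They were 0.953 to 0.956 between DPhP and control libraries.

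**Figure D1:**
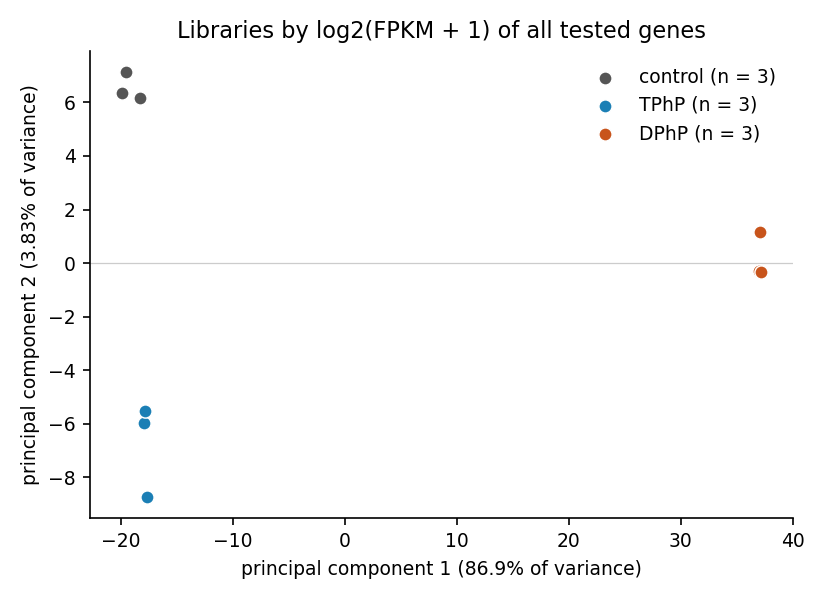
Scores of the 9 libraries on the first 2 principal components of log2(FPKM + 1) over 12369 genes, with the share of variance on each axis; each point is 1 library, coloured by group. DPhP libraries lie near 37 on the first component, and the control and TPhP libraries between -19.9 and -17.6.

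The first comparison asked which genes TPhP changed. Of all tested genes 6.22% were called. Genes of cholesterol synthesis rose together in the TPhP libraries. Lss, which encodes lanosterol synthase (chromosome 10, 76531565 to 76557139 in GRCm38.p6), had the largest rise of the list, to 52.1 ± 2.73 FPKM in TPhP libraries (SD, n = 3; log2 fold change 0.73 against control, SE 0.042, adjusted p = 2.22e-06). Hmgcs1, the cytosolic HMG-CoA synthase, went from 181 ± 2.71 to 272 ± 3.41 FPKM (log2 fold change 0.58, adjusted p = 4.26e-07). Cyp51, the lanosterol demethylase, went from 69.4 ± 1.24 to 107 ± 3.26 FPKM, and Hsd17b7, Tm7sf2 and Mvd, which encode other enzymes of the pathway, rose by log2 fold changes of 0.65, 0.63 and 0.60. Of the 24 tested members of the list 23 rose, none fell, and all 24 were higher when adjusted over the list alone. The list's median log2 fold change was 0.47 (camera adjusted p = 1.78e-44), and the call held with an estimated correlation (adjusted p = 0.0108 with an estimated correlation).

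Genes of fatty acid synthesis moved in the same direction. Of 18 tested members 12 rose and 6 did not pass, and adjusted over the list alone 13 were higher and 1 was lower. The stearoyl-CoA desaturase gene Scd1 rose from 66.1 ± 0.251 to 102 ± 2.82 FPKM (log2 fold change 0.62, adjusted p = 4.26e-07). Its relative Scd2 rose by a log2 fold change of 0.43, Acly (ATP citrate lyase) by 0.37 and Fasn (fatty acid synthase) by 0.32. The list's median was 0.28 (camera adjusted p = 1.34e-13, adjusted p = 0.0765 with an estimated correlation). Acsl3, an acyl-CoA synthetase outside the list, rose from 8.53 ± 0.107 to 13.6 ± 1.08 FPKM (log2 fold change 0.61, adjusted p = 3.81e-05). In the list of cholesterol transport and storage 3 of 19 members rose and 1 fell, with 5 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0564). Among them the sterol exporter genes Abca1 and Abcg1 rose by log2 fold changes of 0.21 and 0.30, and the lipoprotein receptor gene Scarb1 fell by 0.16 on the log2 scale.

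The steroidogenic panel moved little under TPhP. Star, which encodes the protein that carries cholesterol into mitochondria, was at 31.7 ± 1.96 FPKM in control and 35.9 ± 1.45 in TPhP libraries (log2 fold change 0.18, adjusted p = 0.0516), just outside the threshold, and it passed under 6 of the alternatives. Cyp11a1, the side-chain cleavage enzyme that opens steroid synthesis, had a log2 fold change of 0.09 (95% interval 0.02 to 0.16, adjusted p = 0.116), and it passed with quantile normalization alone (0.11, adjusted p = 0.0375). The intervals were -0.05 to 0.12 for Hsd3b1, -0.02 to 0.27 for the luteinizing hormone receptor gene Lhcgr, -0.10 to 0.13 for Insl3 and -0.13 to 0.03 for Nr5a1. Cyp17a1 was listed at 0.08 to 0.25 FPKM in control and TPhP libraries, and Hsd17b3 at 0 to 0.04, so neither could be compared. As both were near 0 in control cells already, these libraries cannot show a fall of either gene. Of 16 tested members of the steroidogenesis list, Hsd3b6 rose (24.6 ± 0.649 to 31.2 ± 0.930 FPKM, log2 fold change 0.33) and Hsd11b1, which interconverts active and inactive glucocorticoids, fell (16.8 ± 0.492 to 10.3 ± 0.808 FPKM, log2 fold change -0.66). The other 14 did not pass, 3 rose and 2 fell adjusted over the list alone, and the list was not called (camera adjusted p = 0.803).

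**Figure D2:**
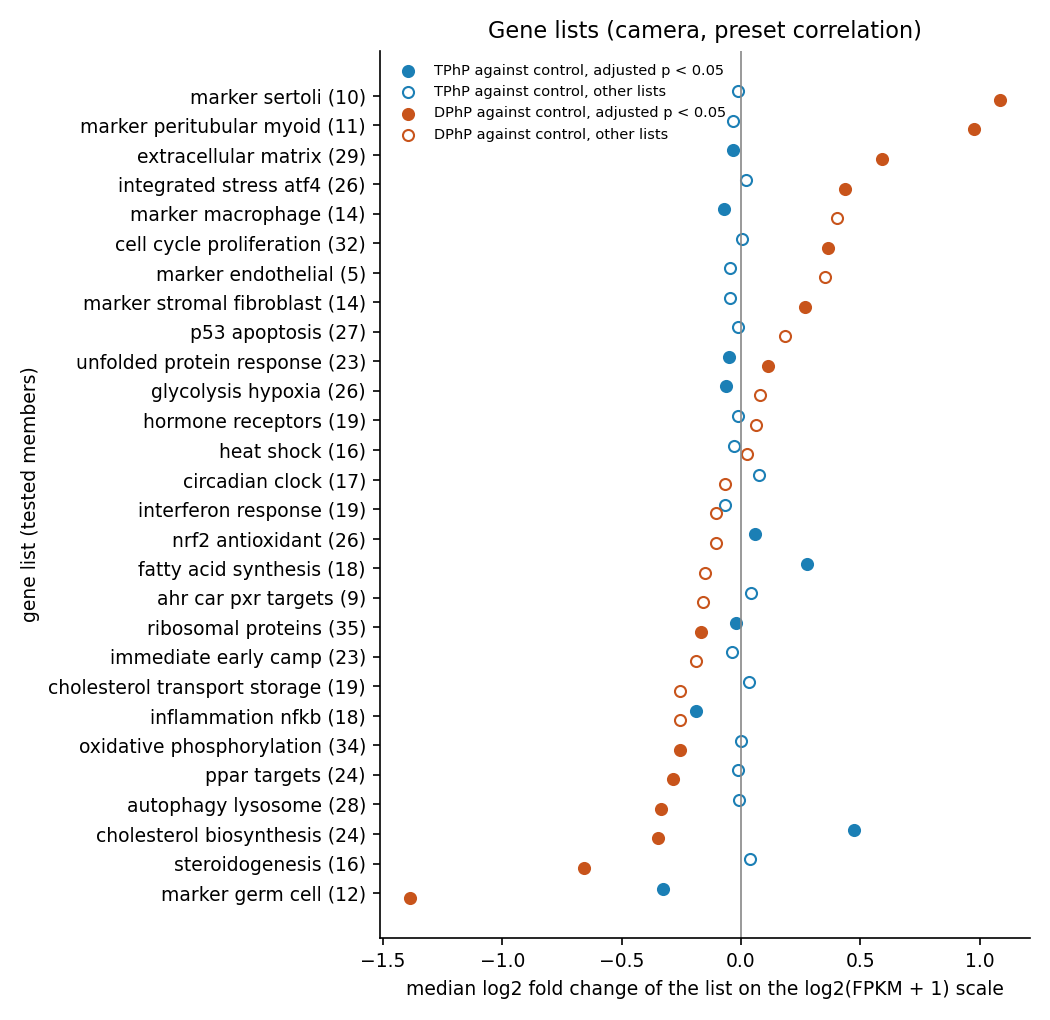
Median log2 fold change, on the log2(FPKM + 1) scale, of 28 gene lists fixed before the data were examined, for TPhP and DPhP against control; filled points have a camera adjusted p under 0.05 at the preset correlation, and numbers in brackets are tested members. Cholesterol biosynthesis lies at 0.47 under TPhP and -0.35 under DPhP, and several cell type marker lists move under DPhP.

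Among genes that fell with TPhP, the alarmin gene Il33 went from 2.50 ± 0.0862 to 0.877 ± 0.0208 FPKM (log2 fold change -0.90, adjusted p = 1.3e-05). Ptpn5, a protein tyrosine phosphatase gene, fell from 12.2 ± 0.657 to 6.60 ± 0.639 FPKM (log2 fold change -0.80). The betaine-homocysteine methyltransferase gene Bhmt and the interferon-inducible gene Ifi205 fell by 0.76 and 0.71 on the log2 scale. Hspb9 and Spata4, at 1.86 ± 0.609 and 2.04 ± 0.897 FPKM in control, were also lower (log2 fold changes -0.76 and -0.69, adjusted p = 0.0251 and 0.0312). Their calls were lost in 6 and 8 of the alternatives, among them leaving out control 2, TPhP 2 or TPhP 3. The largest fall was that of the alpha globin gene Hba-a1 (log2 fold change -2.66, adjusted p = 9.79e-06), which has 37.8% unique sequence. Summed with its near-identical copy Hba-a2, alpha globin was at 8.62 ± 2.18 FPKM in control and 5.93 ± 1.64 in TPhP libraries, and Hba-a2 alone was at 1.91 ± 1.81 and 5.65 ± 1.26 FPKM.

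A further 8 list calls were smaller. Of 18 tested NF-κB and inflammation genes Vcam1, which encodes an adhesion molecule, rose (log2 fold change 0.32), while Nfkbia, which encodes an inhibitor of NF-κB, and the cytokine gene Lif fell (log2 fold changes -0.54 and -0.32). Adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.00137, adjusted p = 0.608 with an estimated correlation). Of 26 glycolysis and hypoxia genes Aldoc rose, and Adm, which encodes adrenomedullin, and Gapdh fell (log2 fold changes 0.32, -0.30 and -0.10), with 1 and 6 adjusted over the list alone (adjusted p = 0.0027, adjusted p = 0.467 with an estimated correlation). Of 12 germ cell markers the spermatogonial gene Zbtb16 and Ddx4 fell (log2 fold changes -0.61 and -0.43) and 4 fell adjusted over the list alone (adjusted p = 0.00764, adjusted p = 0.53 with an estimated correlation). Of 14 macrophage markers Csf1r and Cx3cr1 fell (log2 fold changes -0.22 and -0.30), and 4 fell adjusted over the list alone (adjusted p = 0.0194, adjusted p = 0.376 with an estimated correlation). Of 26 antioxidant genes of the Nrf2 response 4 rose, among them Cat (catalase, log2 fold change 0.14) and Osgin1 (0.23), and 5 rose adjusted over the list alone (adjusted p = 0.0268, adjusted p = 0.53 with an estimated correlation). Of 23 unfolded protein response genes the chaperone genes Pdia6, Calr, Pdia3 and Hspa5 fell, by 0.10 to 0.17 on the log2 scale, and 1 rose and 5 fell adjusted over the list alone (adjusted p = 0.0299, adjusted p = 0.254 with an estimated correlation). The ribosomal protein list, with 1 of 35 members lower and 0 adjusted over the list alone, and the extracellular matrix list, with 1 of 29 higher and 5 lower and 3 and 8 adjusted over the list alone, were at the threshold (adjusted p = 0.0499 for both). With an estimated correlation their adjusted p was 0.795 and 0.53.

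Of these 8 calls, that of glycolysis and hypoxia held with camera at the preset correlation in all 22 alternatives of data and model (adjusted p 9.09e-05 to 0.0409) and was lost with an estimated correlation (adjusted p = 0.467) and with directional fry (adjusted p = 0.0900). The other 7 each ended without at least 1 single library. Of these 7, directional fry called the unfolded protein response and macrophage lists (adjusted p = 0.00969 and 0.0367) and none of the others (0.103 to 0.434). Heat shock and cholesterol transport, which camera did not call, also passed with directional fry (adjusted p = 0.00946 and 0.0196). Without control 1 the germ cell and antioxidant calls ended (adjusted p = 0.145 and 0.101), and without control 2 the inflammation and ribosomal calls (0.0657 and 0.324). Without control 3 the extracellular matrix, macrophage, antioxidant and unfolded protein response calls ended (0.215, 0.0629, 0.117 and 0.122). Without TPhP 2 the extracellular matrix call ended (0.219), and without TPhP 3 the ribosomal and unfolded protein response calls (0.569 and 0.0619). The extracellular matrix call also ended without DPhP 3 (0.0612), and the ribosomal call without DPhP 2 (0.0586). Over the alternatives of data and model the adjusted p ranged from 0.0194 to 0.787 for extracellular matrix, 0.00387 to 0.876 for ribosomal proteins, 0.00824 to 0.122 for the unfolded protein response and 0.00232 to 0.105 for macrophage markers. The ranges were 0.00108 to 0.117 for antioxidant genes, 6.73e-05 to 0.145 for germ cell markers and 1.67e-05 to 0.0657 for inflammation. Among the genes named with these lists, the calls of Lif, Aldoc, Gapdh, Ddx4, Cx3cr1, Osgin1, Calr, Pdia3 and Hspa5 all ended without control 2 (adjusted p 0.0511 to 0.115) and without TPhP 2 (0.0514 to 0.0812), and each of them also without at least 1 other library. That of Cat ended without TPhP 1 (0.0592).

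The remaining 18 lists were not called, with camera adjusted p between 0.0564 and 0.967. Of 23 genes of the immediate early and cAMP response 4 fell and none rose, with 5 adjusted over the list alone, among them Klf4, Sik1, Myc and Per1 (log2 fold changes -0.23, -0.29, -0.20 and -0.21). These 4 calls were lost in 2, 4, 9 and 8 of the alternatives. That of Klf4 ended without control 2 or TPhP 2 (adjusted p = 0.0512 and 0.0534), and the other 3 each ended without control 1, control 3, TPhP 1 or TPhP 3 (0.0528 to 0.114), Myc also without control 2 (0.120) and Per1 without TPhP 2 (0.105). Of 16 heat shock genes 3 fell, over all genes and adjusted over the list alone, led by Hspa1b (log2 fold change -0.42), which has 44.2% unique sequence. The other 2 calls, of Dnaja1 and Hspb1, were lost in 13 and 12 of the alternatives, among them rescaling to a common sum (adjusted p = 0.0838 and 0.0635) and leaving out control 1, control 3 or any 1 of the TPhP libraries (0.0612 to 0.134). The targets of peroxisome proliferator-activated receptors had Plin2, a lipid droplet coat gene, higher (log2 fold change 0.18) and Pdk4 and Angptl4 among the 3 lower (-0.36 and -0.17), with 3 and 4 of 24 adjusted over the list alone. The Plin2 call ended without control 2 or control 3 (0.0619 and 0.0514), and the Angptl4 call without control 2 or TPhP 2 (0.0775 and 0.0895). Of the other lists, higher and lower members numbered 2 and 2 of 17 for clock genes (3 and 3 adjusted over the list alone), 2 and 2 of 26 for ATF4 targets (3 and 3), 1 and 1 of 27 for p53 targets (3 and 2), 2 and 0 of 28 for autophagy (5 and 1), 3 and 2 of 14 for stromal fibroblast markers (3 and 3), 1 and 0 of 11 for myoid (1 and 1), 0 and 1 of 10 for Sertoli (0 and 1) and 0 and 1 of 4 for blood cell markers (1 and 1). No member passed of 32 cell cycle, 34 oxidative phosphorylation, 19 hormone receptor, 19 interferon, 9 xenobiotic receptor and 5 endothelial genes, where 3 hormone receptor genes were higher and 1 lower adjusted over the list alone, and none in the other 5. Medians and tests had different signs, all without a call, for the cell cycle, oxidative phosphorylation, p53, hormone receptor and autophagy lists, and the stromal median was -0.05 with a mean of 0.003.

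In all, limma called 769 of 12369 genes between TPhP and control, 319 higher and 450 lower, with a median absolute log2 fold change of 0.21. After rescaling each library to a common sum the split turned to 432 higher and 355 lower of 787. Of the called genes, only Hba-a1 and the histone gene H2ac11 (log2 fold change -1.01, 22.4% unique sequence; chosen after its values were seen) reached a log2 fold change of 1 in either direction, and Hba-a2 stood at 1.43 without a call (adjusted p = 0.0649). The groups did not overlap in 27.3% of tested genes, against 10% by chance. The number of genes changed, TPhP against control, was 504, 444, 436 and 413 without control 1, control 2, TPhP 1 and TPhP 2, respectively.

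The second comparison asked which genes DPhP changed, and it gave far larger differences. As 71.0% of all tested genes were called, a count of called members, whatever their direction, does not by itself set a list apart. Adjustment over the list alone then changes few counts and is no separate support. Genes of Leydig cell function fell in the DPhP libraries. Insl3, which encodes the Leydig cell hormone insulin-like 3 (chromosome 8, 71689252 to 71690577 in GRCm38.p6), fell from 537 ± 17.2 FPKM in control to 11.3 ± 1.02 FPKM in DPhP libraries (log2 fold change -5.45, SE 0.052, adjusted p = 1.43e-14, n = 3 each). Hsd3b6, a 3β-hydroxysteroid dehydrogenase gene (chromosome 3, 98805504 to 98814443), fell from 24.6 ± 0.649 to 0.18 ± 0.04 FPKM (log2 fold change -4.44). Its relative Hsd3b1 fell from 626 ± 26.7 to 146 ± 4.29 FPKM and Cyp11a1 from 490 ± 21.3 to 113 ± 2.07 FPKM (log2 fold changes -2.09 and -2.11). Lhcgr and Nr5a1, which encodes steroidogenic factor 1, fell by 0.64 and 0.53 on the log2 scale. Star was at 31.1 ± 1.21 FPKM against 31.7 ± 1.96 in control (log2 fold change -0.03, 95% interval -0.13 to 0.08, adjusted p = 0.638). Of 16 members of the steroidogenesis list 13 fell and 1 rose, both over all genes and adjusted over the list alone (median log2 fold change -0.66, camera adjusted p = 2.37e-05, adjusted p = 0.0846 with an estimated correlation). Insl3 has 39.9% unique sequence.

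**Figure D3:**
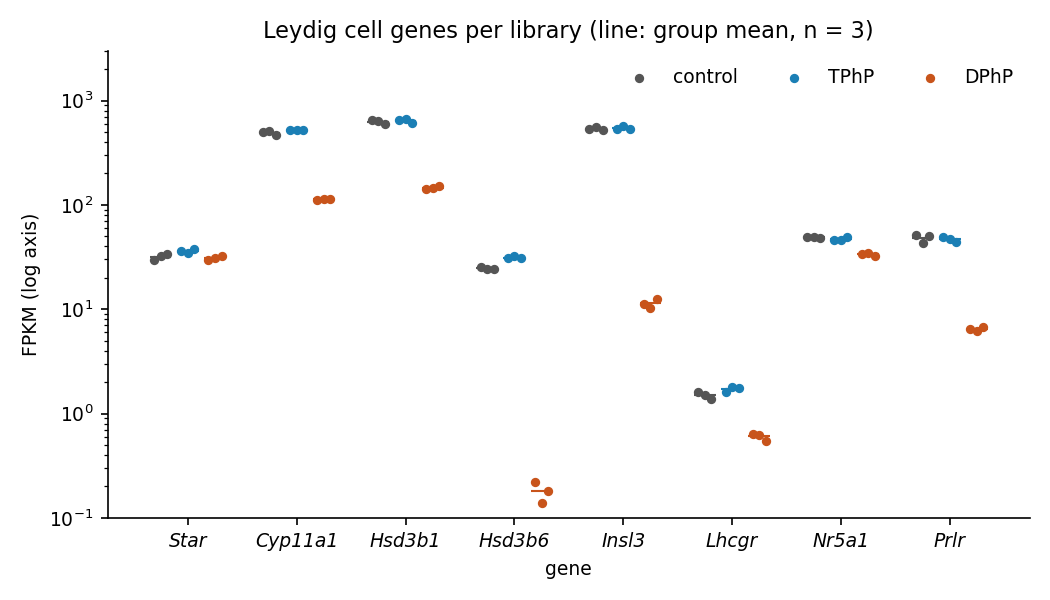
FPKM on a log axis of 8 Leydig cell genes in each of the 9 libraries; points are libraries, short lines the group means (n = 3). Star has group means from 31.1 to 35.9 FPKM, while Insl3, Hsd3b6, Hsd3b1, Cyp11a1, Lhcgr, Nr5a1 and the prolactin receptor gene Prlr are lower in DPhP libraries.

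Cholesterol synthesis genes moved the opposite way to TPhP. Of 24 members 22 fell and 2 rose, both over all genes and adjusted over the list alone (median log2 fold change -0.35, camera adjusted p = 2.51e-05, adjusted p = 0.161 with an estimated correlation). Sc5d went from 85.8 ± 1.58 to 29.7 ± 1.67 FPKM and Msmo1 from 205 ± 7.03 to 94.0 ± 5.77 FPKM (log2 fold changes -1.50 and -1.12). Dhcr7, which encodes 7-dehydrocholesterol reductase, fell by 0.67 on the log2 scale. Of 18 fatty acid synthesis genes 6 rose and 10 fell, over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.475). Scd1 rose by a log2 fold change of 0.42, while Me1 (malic enzyme) fell from 663 ± 3.87 to 334 ± 6.64 FPKM.

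Genes of fat use and respiration fell as well. Of 24 targets of peroxisome proliferator-activated receptors 18 fell and 1 rose, also adjusted over the list alone (median -0.28, adjusted p = 4.94e-05, adjusted p = 0.0861 with an estimated correlation). Pdk4, Angptl4 and Fabp3 fell by 1.70, 1.66 and 1.56 on the log2 scale. Of 34 nuclear genes of oxidative phosphorylation 28 fell and 1 rose, also adjusted over the list alone (median -0.26, adjusted p = 4.2e-05, adjusted p = 0.199 with an estimated correlation). Ndufb8 and Ndufa1, subunits of complex I, each fell by 0.77. Over the alternatives these medians ranged from -0.50 to -0.20 and from -0.27 to -0.12. Of 28 autophagy and lysosome genes 22 fell and 3 rose, 23 and 3 adjusted over the list alone (median -0.34, adjusted p = 0.00012, adjusted p = 0.0846 with an estimated correlation), among them Map1lc3a (log2 fold change -0.74) and Sqstm1 (-0.57). Of 35 ribosomal protein genes 25 fell and 3 rose, also adjusted over the list alone (median -0.17, adjusted p = 0.00474, adjusted p = 0.413 with an estimated correlation). That call ended with quantile normalization, with unique genes alone and, with its median turned to 0.04, after removal of GC and length trends (adjusted p = 0.612; range over the alternatives 0.00107 to 0.612). Lower and higher ribosomal members numbered 14 and 9 with quantile normalization and 18 and 6 after rescaling to a common sum.

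Markers of other cell types moved with DPhP too, in both directions. Of 11 peritubular myoid markers 10 rose and 1 fell, also adjusted over the list alone (median 0.98, adjusted p = 3.99e-05, adjusted p = 0.118 with an estimated correlation), led by the smooth muscle actin genes Actg2 (6.86 ± 0.840 to 26.8 ± 1.53 FPKM) and Acta2 (350 ± 22.5 to 923 ± 25.3 FPKM). Of 14 stromal fibroblast markers 10 rose and 2 fell, also adjusted over the list alone (median 0.27, adjusted p = 0.0107, adjusted p = 0.0991 with an estimated correlation), with Fbln1 and Mfap5 higher by log2 fold changes of 2.00 and 1.98. Of 10 Sertoli cell markers 7 rose and 3 fell, also adjusted over the list alone (median 1.09, adjusted p = 0.0244, adjusted p = 0.299 with an estimated correlation). Cldn11 rose by a log2 fold change of 2.03 and Trf, with 21.4% unique sequence, fell by 1.04. The Sertoli call ended under a mean of at least 5 FPKM, rescaling to a common sum and quantile normalization (adjusted p = 0.0948, 0.0861 and 0.0531; range 0.0126 to 0.0948), and its median ranged from 0.24, without a filter on low values, to 1.29. Of 12 germ cell markers 10 fell and 1 rose, also adjusted over the list alone (median -1.39, adjusted p = 0.00887, adjusted p = 0.413 with an estimated correlation). Their median ranged from -3.05, with a pseudocount of 0.1, to -0.71, without a filter. The protamine genes Prm1 and Prm2, which package spermatid DNA, were at 8.77 ± 3.06 and 9.04 ± 4.02 FPKM in control. In the 3 DPhP libraries Prm1 averaged 0.0933 FPKM and Prm2 was listed at 0. All 4 tested blood cell markers fell (median -2.83), and the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were listed at 0 in all DPhP libraries. The call of Hba-a2 ended without control 1 or control 2 (adjusted p = 0.0546 and 0.0648). The macrophage list (8 of 14 higher, 4 lower) and the endothelial list (3 of 5 higher) were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.149 and 0.122).

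Extracellular matrix genes rose alongside the myoid and stromal markers, whose medians were 0.98 and 0.27, in libraries where the Leydig genes above fell. Of 29 members 20 rose and 7 fell, also adjusted over the list alone (median log2 fold change 0.59, adjusted p = 0.000109, adjusted p = 0.145 with an estimated correlation). The proteoglycan gene Bgn rose from 438 ± 11.5 to 1344 ± 29.8 FPKM, and the collagen genes Col1a1 and Col1a2 by log2 fold changes of 1.49 and 1.19. Of 32 cell cycle genes 26 rose and none fell, with 27 adjusted over the list alone (median 0.36, adjusted p = 1.17e-07, adjusted p = 0.0861 with an estimated correlation), with Top2a at 36.2 ± 0.295 and 60.3 ± 0.151 FPKM and Mki67 higher by a log2 fold change of 0.71. Of 26 genes of the ATF4 stress response 18 rose and 5 fell, also adjusted over the list alone (median 0.44, adjusted p = 0.000847, adjusted p = 0.0991 with an estimated correlation). Asns, asparagine synthetase, went from 18.5 ± 1.02 to 47.7 ± 0.930 FPKM, and Atf3 fell by 1.14 on the log2 scale. Of 23 unfolded protein response genes 13 rose and 4 fell, also adjusted over the list alone (median 0.11, adjusted p = 0.0152, adjusted p = 0.0991 with an estimated correlation), among them the chaperone genes Hspa5 and Hsp90b1 (log2 fold changes 0.48 and 0.49).

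Among the genes taken by the naming rule, which leaves out symbols with a Gm number or a Rik name, the largest rises were those of Ctsk, Cck and Ifi204. Ctsk, which encodes the collagen-degrading protease cathepsin K (chromosome 3, 95499210 to 95509387), went from 0.39 ± 0.03 to 72.1 ± 0.674 FPKM (log2 fold change 5.72, adjusted p = 1.43e-14). Cck, a peptide hormone gene, went from 0.26 ± 0.02 to 19.5 ± 1.42 FPKM, and the interferon-inducible gene Ifi204 from 10.5 ± 1.28 to 132 ± 4.67 FPKM. The microfibril gene Mfap4, the Wnt antagonist gene Sfrp1, Emb and the growth factor gene Mdk rose by log2 fold changes of 2.96 to 3.13. Besides Insl3 and Hsd3b6, the largest falls among them were those of Alb, Ly6k, Hbb-bs, Zfp979 and LOC100862446. Alb, which encodes serum albumin, was at 19.7 ± 3.86 FPKM in control and listed at 0 in the 3 DPhP libraries. Ly6k went from 72.5 ± 5.02 to 5.04 ± 0.204 FPKM. Hbb-bs and LOC100862446 have 35.7% and 11.1% unique sequence.

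In all 14 lists without a call the camera adjusted p lay between 0.117 and 0.871. In the 11 not yet named, the counts of higher and lower members were 13 and 7 of 26 for glycolysis and hypoxia, 5 and 12 of 19 for cholesterol transport, 5 and 14 of 26 for the Nrf2 response, 6 and 12 of 23 for immediate early genes and 15 and 10 of 27 for p53 targets. They were 2 and 5 of 9 for xenobiotic receptor targets, 5 and 9 of 18 for inflammation, 6 and 8 of 17 for clock genes, 2 and 6 of 19 for interferon genes, 9 and 8 of 19 for hormone receptors and 7 and 7 of 16 for heat shock. Adjusted over the list alone these were the same except for cholesterol transport (5 and 13), inflammation (5 and 10) and interferon genes (2 and 3). All these counts stand beside the 71.0% of all tested genes that were called. Members with larger changes included Vegfa (log2 fold change 1.26), Abca1 (-1.26), Sod1 (-0.83), Prlr (-2.72), Lcn2 (-2.32) and the aldehyde dehydrogenase gene Aldh3a1 (-1.08). The hormone receptor list had a median of 0.06 and a mean of -0.21, and the heat shock list a median of 0.02 and a mean of -0.05, with camera lower for the first and higher for the second.

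In all, limma called 8782 of 12369 genes between DPhP and control, 4089 higher and 4693 lower, and 694 of them with a log2 fold change of at least 1 in either direction (294 higher, 400 lower). After rescaling to a common sum the split was 5212 higher and 3726 lower of 8938, with the median of all genes moving from -0.02 to 0.06. The groups did not overlap in 73.4% of tested genes, against 10% by chance. As exposure was the same for all 3 DPhP libraries, any other way in which they differed as a group could not be separated from it.

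The third comparison set the parent compound against the metabolite that lacks 1 phenyl ester. As no dose or time is given for either, the exposures are not known to be matched. Of all tested genes 68.7% were called here, so the limit on counts of members given for DPhP against control holds here too. Cholesterol synthesis genes were higher with TPhP than with DPhP in 22 of 24 members, both over all genes and adjusted over the list alone (median log2 difference 0.80, camera adjusted p = 9.62e-11, adjusted p = 0.0617 with an estimated correlation). The difference was 1.90 for Sc5d, 1.63 for Msmo1, 1.47 for Tm7sf2 and 1.20 for Lss.

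Steroidogenic genes were higher with TPhP in 14 of 16 members and lower in 2, also adjusted over the list alone (median 0.74, adjusted p = 1.69e-05, adjusted p = 0.0617 with an estimated correlation). The differences were 5.47 for Insl3 (95% interval 5.35 to 5.58), 4.77 for Hsd3b6, 2.20 for Cyp11a1, 2.13 for Hsd3b1, 0.77 for Lhcgr, 0.48 for Nr5a1 and 0.20 for Star (0.10 to 0.31, adjusted p = 0.00257). Fatty acid synthesis was higher in 13 of 18 members and lower in 1, also adjusted over the list alone (median 0.36, adjusted p = 0.00185, adjusted p = 0.222 with an estimated correlation). Elovl6, an elongase gene, differed by 0.84 and Me1 by 1.08. The autophagy list (22 higher, 1 lower of 28; median 0.29, adjusted p = 2.82e-05), the receptor targets of fat use (19 and 1 of 24; median 0.39, adjusted p = 2.82e-05) and oxidative phosphorylation (28 and 2 of 34; median 0.21, adjusted p = 2.96e-05) were also higher with TPhP, with the same counts adjusted over the list alone. With an estimated correlation these had an adjusted p of 0.0617, 0.0617 and 0.202. Over the alternatives the median ranged from 0.24 to 0.54 for the receptor targets and from 0.12 to 0.22 for oxidative phosphorylation.

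Lower with TPhP than with DPhP were cell cycle genes (29 of 32; median -0.38, adjusted p = 5.15e-09), extracellular matrix (21 of 29, with 7 higher; median -0.62, adjusted p = 2.28e-05), ATF4 targets (18 of 26, with 7 higher; median -0.39, adjusted p = 0.00118) and the unfolded protein response (13 of 23, with 5 higher; median -0.15, adjusted p = 0.00348). The counts were the same adjusted over the list alone, and with an estimated correlation the adjusted p was 0.0617, 0.0941, 0.0782 and 0.0617. Glycolysis and hypoxia genes were lower in 14 of 26 members and higher in 6, also adjusted over the list alone (median -0.18, adjusted p = 0.0169, adjusted p = 0.405 with an estimated correlation). Col1a1 differed by -1.61, Mmp3, a matrix protease gene, by -2.32, Ccnd1 (cyclin D1) by -1.12 and Asns by -1.16. Markers of other cell types moved with these lists. They were lower with TPhP for peritubular myoid (10 of 11; median -0.85, adjusted p = 1.13e-05), stromal fibroblast (9 of 14, with 3 higher; median -0.33, adjusted p = 0.0103) and Sertoli cells (7 of 10, with 2 higher; median -1.18, adjusted p = 0.0133). Germ cell markers were higher in 9 of 12 and lower in 1 (median 1.06, adjusted p = 0.0392), and 3 of 4 blood cell markers were higher. These counts were the same adjusted over the list alone, and the estimated correlation gave an adjusted p of 0.0816, 0.0811, 0.222 and 0.481. Without DPhP 1 the germ cell call ended (adjusted p = 0.0531; range 0.00548 to 0.0531). The Sertoli call ended with a mean of at least 5 FPKM (0.0714; range 0.00568 to 0.0714), and the glycolysis call with unique genes alone (0.0562; range 0.00164 to 0.0562). Over the alternatives the medians ranged from 0.55 to 2.54 for germ cell, -1.28 to -0.37 for Sertoli and -1.28 to -0.73 for myoid markers. Ribosomal protein genes were higher in 18 of 35 and lower in 1, also adjusted over the list alone (median 0.12, adjusted p = 0.0198, adjusted p = 0.481 with an estimated correlation). That call ended under 4 alternatives (adjusted p 0.00679 to 0.450 over all of them), and its median turned to -0.07 after removal of GC and length trends. Higher and lower ribosomal members numbered 14 and 9 with quantile normalization and 16 and 5 after rescaling to a common sum.

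The 12 lists without a call in this comparison had camera adjusted p of 0.0625 to 0.873. Higher and lower members with TPhP numbered 11 and 5 of 19 for cholesterol transport (12 and 5 adjusted over the list alone), 4 and 9 of 14 for macrophage, 0 and 3 of 5 for endothelial, 15 and 5 of 26 for Nrf2 genes, 5 and 2 of 9 for xenobiotic receptor targets and 8 and 12 of 27 for p53 targets. They were 7 and 3 of 17 for clock genes, 8 and 6 of 19 for hormone receptors (8 and 7), 6 and 7 of 16 for heat shock, 11 and 10 of 23 for immediate early genes (11 and 11), 3 and 2 of 19 for interferon genes (3 and 1) and 5 and 7 of 18 for inflammation. In the inflammation list the median was 0.08 while the mean was -0.02 and camera was lower. In all, limma called 8495 genes between TPhP and DPhP, 4672 higher and 3823 lower with TPhP, and 660 with a log2 difference of at least 1 in either direction. The split was 3805 higher and 4763 lower of 8568 after rescaling to a common sum and 4097 and 4374 with quantile normalization.

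The fold changes of both compounds against their shared control had a Pearson correlation of 0.218 across genes, which are not independent replicates. Unchanged groups simulated against the same controls gave 0.502. The covariance was 0.0134, against 0.00299 in the simulation, a difference of 0.0104. In total 663 genes were called with both compounds, 141 higher and 290 lower with both, against 105 and 171 for independent lists and 0 in the simulation. Higher with TPhP and lower with DPhP were 132 genes, against 121, and 100 showed the reverse, against 149. The simulation holds no effects, and independent lists share no controls, so the excess over either was not taken as a shared effect. The 3 controls were not split, as a part would have held 1 library. Of the 769 genes called with TPhP, 665 also differed directly between the compounds, where 68.7% of all tested genes were called. Of 106 genes called with TPhP and not with DPhP, 96 differed directly in the same direction. The same TPhP libraries enter both comparisons, and the 106 were picked for a change with TPhP alone. That count is therefore largely built in and is no evidence of an effect particular to TPhP. Of the 694 genes with a log2 fold change of at least 1 under DPhP, 127 were called with TPhP, where 6.22% of all tested genes were called. In 587 of the 694 the 95% interval of the TPhP effect lay within 0.5 of 0, and the share over all tested genes was not computed. Both effects use the same 3 control libraries, so neither count is evidence of a shared or a separate effect.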

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

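The tests of a lower Leydig cell share and of a separate preparation, and the removal of GC and length trends, were chosen only after the results were seen. TPhP and DPhP moved 3 lists in opposite directions from the control. They did the same to 9 of the genes named for the largest changes or as the Leydig panel. A call between the compounds was also required of each. For genes called in opposite directions against the same control that call was bound to follow, so it adds no support. Over all tested genes 132 were called higher with TPhP and lower with DPhP, against 121 for independent lists, and 100 the reverse, against 149. Genes named only as list members are not counted in the 9. Others of these, such as Msmo1 and Sc5d, moved in opposite directions as well. The median log2 difference, TPhP minus DPhP, was 0.80 for cholesterol biosynthesis, -0.62 for extracellular matrix and -0.15 for the unfolded protein response. Among genes it was 1.20 for Lss, 1.47 for Tm7sf2, 1.14 for Hsd17b7, 1.02 for Cyp51, 0.81 for Mvd and 4.77 for Hsd3b6, all higher with TPhP. It was -4.28 for Cck, -3.78 for Ifi204 and -0.97 for Ptpn5. Cck averaged 0.26 FPKM in control and 0.0567 in TPhP libraries, and it passed the filter only through the DPhP libraries. Its fall under TPhP therefore lies near 0, where no counting limit is known. The calls against control were near the threshold for Cck and Ifi204 under TPhP (adjusted p = 0.0468 and 0.0464) and for Ptpn5 under DPhP (0.0251). Under TPhP the extracellular matrix call (median -0.03, adjusted p = 0.0499, 0.53 with an estimated correlation) was lost in 12 of 22 alternatives and the unfolded protein response call (median -0.05, 0.0299, 0.254 with an estimated correlation) in 5, so their opposite directions rest on weak calls. With an estimated correlation the cholesterol list had an adjusted p of 0.0108 under TPhP, 0.161 under DPhP and 0.0617 between the compounds, and those of the other lists between the compounds were 0.0941 and 0.0617.

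With 3 libraries against 3, there are 10 splits, too few for a share under 0.05. Of them 1 split, the real one, gave as many genes in each comparison. The real split gave 769 genes for TPhP against control and the highest other 0 in limma, with 381 to 655 genes at an unadjusted p under 0.05 in the other splits. For DPhP against control these were 8782 and 1, and for TPhP against DPhP 8495 and 1.

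The first pattern is that 8782 genes differed between DPhP and control libraries. Scaling as the whole cause is argued against, as 8770 genes were called under the scaling with the fewest, and so is a trend with GC content or length, as 8119 were called after its removal. A lower share of Leydig cells with other cell types unchanged would raise all other markers alike. The stromal fibroblast list, called higher, and the germ cell list, called lower, had medians 1.66 apart on the log2 scale. These were the closest marker lists that moved apart. With an estimated correlation their adjusted p was 0.0991 and 0.413, so neither call held. The gap argues only against the form with all other cell types unchanged. A shift of several cell types at once, such as fewer Leydig, germ and blood cells together, was not tested and stays open. A separate preparation of the DPhP libraries and an effect of DPhP cannot be told apart, as both would fall on the same 3 libraries. The markers taken were the 14 of germ and blood cells found in all 6 other libraries at a control mean of at least 1 FPKM. Their median DPhP to control ratio was 0.0191, against 0.711 for TPhP to control. As presence was required in the TPhP libraries and not in the DPhP libraries, part of this contrast is built in. A difference in the age or strain of the donors might also act here and was not tested.

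The second pattern is the opposite movement of cholesterol genes. Scaling is argued against, as the smallest TPhP median and the largest DPhP median under the 3 other scalings stayed 0.744 apart, and so are GC and length trends, with a gap of 0.788 after their removal. In a response of the TPhP cells to lower sterol, liver X receptor targets would fall. As a set they rose instead, with a median log2 fold change of 0.08. The p of fry for this set was 0.00186, which rests on the limma model, and no exact test was run. Of the 9 tested targets, Abca1 and Abcg1 were called higher and none lower. Nr1h3, Lpcat3 and Smpdl3a had log2 fold changes of -0.17, -0.02 and -0.01 without a call. The predicted fall was not seen. The rise rests on 2 genes, which TPhP could raise by another route, so lower sterol stays open. No other explanation of the rise under TPhP was tested. The part under DPhP shares the open question of the preparation.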

How the results depend on the processing

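The restriction to unique genes and the removal of GC and length trends were chosen after seeing the data. Of 7264 alternative values of the named genes 7004 kept their side of the threshold without reversing a call, 253 lost the call, 7 gained it and 0 called values reversed, while 6 values without a call, of Star under DPhP and Insl3 under TPhP, changed sign. Of 877 values of named lists 829 kept direction and side of the threshold, and 46 lost the call. The median of the ribosomal list reversed after removal of GC and length trends, to 0.0432 under DPhP and -0.0679 between the compounds, and the cause was not tested. With a log2 fold change of at least 1 required, 2, 694 and 660 genes were called for TPhP against control, DPhP against control and TPhP against DPhP, by the construction of that threshold. Lists called in the same order were 1, 0 and 0 with an estimated correlation, 6, 26 and 26 with directional fry and 24, 28 and 28 with mixed fry, which ask other questions. With a mean of at least 5 FPKM 6 lists were called for TPhP. Leaving out 1 library gave 413 to 775 genes changed, TPhP against control, and 6 to 11 lists, the fewest genes without TPhP 2 and the fewest lists without control 3. The correlation of log2 fold changes, TPhP and DPhP against the shared control, was 0.205 to 0.261 when leaving out 1 library, 0.238 without a filter and 0.173 after removal of the trends. The cause of these moves was not tested. With a replicate block there were 663 genes changed, TPhP against control, 8711 genes changed, DPhP against control, and 8458 genes changed, TPhP against DPhP, with 10, 14 and 16 lists. The numbers did not pair the libraries, as 0 of 9 correlated best with their own number in both other groups. Depth in reads was unknown, so genes listed near 0 carry no counting limit.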

Other observations

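The test on summed beta globin was chosen after its values were seen. The tests on Y-linked genes and on unique sequence were set after the near-zero genes were seen and before the tested values were. Genes outside the naming rule in this part were chosen after their values were seen. Near-identical copies moved differently from their sums. Summed FPKM of Morf4l1 and Morf4l1b was 241 ± 3.07 in control, 248 ± 5.08 in TPhP and 319 ± 5.49 in DPhP libraries (SD, n = 3). The signal recognition particle genes Srp54a, Srp54b and Srp54c summed to 55.7 ± 0.416, 58.7 ± 1.03 and 68.9 ± 1.93 FPKM. Of 9 liver X receptor targets 8 fell and 1 rose under DPhP (median log2 fold change -0.38). The spermatid genes Tnp1 and Tnp2 were at 3.24 and 4.46 FPKM in control and at 0 and 0.0333 in DPhP libraries, while the meiotic gene Sycp3 was at 1.01 and 1.10.

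The third pattern is a set of 14 genes that were at or under 0.5 FPKM either in all DPhP libraries or in all 6 others, and at 5 FPKM or more in all remaining libraries. In the DPhP libraries 11 were missing, among them Alb, Hsd3b6, Prm1 and Prm2, and 3 were present there alone, Ctsk, Cck and Cd300ld4. No gene set the TPhP libraries apart in this way. Genes with under 50% unique sequence made up 28.6% of the set and 4.10% of other tested genes (Fisher exact p = 0.00206; odds ratio 9.36, 95% interval 2.13 to 32.6), and without Hbb-bs 3 of 13 did (Fisher exact p = 0.0146). For Hbb-bs shared reads are argued against, as the summed FPKM of Hbb-bs, Hbb-bt, Hbb-b1 and Hbb-b2 had a DPhP to control ratio of 0.00185, and for the other 3, Gm15501, Gm21451 and Cd300ld4, they may act. For the 8 genes with at least 90% unique sequence shared reads are argued against. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a median log2 fold change of 0.11 under DPhP, which argues against loss of the Y chromosome. All 14 genes lie on autosomes, so such a loss would not by itself remove them, and the test does not bear on the set.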
